A study of Mus musculus with 6 samples.

How the data were processed

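Gene expression was measured on 6 single-colour Affymetrix arrays. Each array held biotin-labelled cRNA made from 250 ng of total RNA of mouse dorsal telencephalon at embryonic day 14.5. Per the labels, 3 arrays are wild type (WT) and 3 are conditional knockouts (cKO) made with Emx2Cre, all on a C57BL\6 background and all labelled male. The design text speaks of 3 male embryos of each genotype, which is taken here as 1 embryo per array. Arrays are named by group and by the number in their titles, as in WT 1.

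The deposited values are array intensities on a linear scale, 1 value per probe set and array. Per the submitters' processing notes they come from the Affymetrix Expression Console. The version and the summary algorithm are not given in the sources used here. The mean intensity after trimming 2% of the probe sets at each end was between 497.2 and 497.7 on every array, so the deposited intensities carry a common scaling. The table analysed here holds no detection calls, so no probe set was classed as present or absent. All 6 sample columns were used.

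Intensities were taken to log2(intensity + 16), and log2 fold changes are differences of group means on that scale, cKO minus WT. The pseudocount makes fold changes of dim genes smaller than the ratio of their intensities. Medians of the arrays differed by 0.33 on this scale, below the 0.5 at which the arrays would have been centred, so no further normalization was applied. Every one of the 45037 probe sets in the table was tested, since none was a control probe set. A linear model with genotype as its only term was fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Errors of fold changes are the moderated standard errors (SE) of that model, and ± after an intensity is the SD of 3 arrays. The 3 arrays per group limit the precision.

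Genes were named from the platform annotation, which gave 1 gene to 34945 probe sets, several genes to 932 and none to 9160. Symbols were compared through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, and 0 of them needed an update. The gene table holds 18193 genes, each represented by the probe set with the highest mean log2 value among those given to that gene alone, and it was fitted and adjusted on its own. Probe sets with several genes or none were kept in the probe set counts and left out of the gene table.

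Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Of 28 lists written for cell types of the embryonic forebrain and its surroundings, germline and early embryo genes, protocadherins, imprinted genes, chromatin, cell cycle and stress responses, 26 had at least 5 measured genes and were tested. A list of sex-linked genes had 4 measured genes and served as a check of the labels. A list of genes with retroviral titles was not made, because the annotation used here holds no gene titles. Counts called adjusted over the list alone use the p-values of the gene table with Benjamini-Hochberg adjustment over the members of that list.

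The genes named in the text follow a rule. It takes Setdb1 with all its probe sets, and in each direction the 15 genes with the largest log2 fold change among those past the threshold whose WT and cKO arrays do not overlap. Names that are clone, accession or predicted-gene names are passed over but stay in the counts. It also takes up to 4 members of each list with the smallest p, and any gene picked out in the closing section's first part, of which there was none. Genes named outside this rule are said to be so. The groups, the main model, the gene lists, this rule and the alternatives named first below were fixed before the data were examined.

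The fit and the calling of genes were tested on simulated arrays with the means and spreads of the 18193 genes and 200 changed genes. In that simulation of cKO against WT, 2% of genes changed 1.5-fold, 30% of those changed 2-fold, 60% of those changed 4-fold and 68% of those changed 8-fold were called in the right direction, with 3 false calls among 83. Of changed genes with an intensity above 200, 50% were called at 2-fold, 88.5% at 4-fold and 100% at 8-fold. In a separate simulation, a list raised by 0.5 on the log2 scale was called, and 0 of the other lists were. Both simulations drew each gene and array independently, so they held no correlation between genes and no shared deviation of arrays. They therefore do not test how such correlation affects the calls of genes or lists.

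The alternatives tried were quantile normalization, centring on array medians, leaving out probe sets below the median mean, pseudocounts of 1 and 64, eBayes with trend and robust settings, array weights, leaving out probe sets whose names end in _x_at or _s_at, the replicate number as a block, each array left out in turn, a fold threshold, and the mean of a gene's probe sets. After the data were seen, fits were added without the arrays numbered 3, with those arrays as a block, and with Xist as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.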

Results

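Transcripts were measured on 6 arrays of dorsal telencephalon, the part of the embryonic forebrain that forms the cerebral cortex. The tissue was taken at an embryonic stage when cortical progenitors are producing neurons. The 3 WT and 3 cKO arrays differ in whether the embryo carried a conditional deletion of ESET, the histone H3 lysine 9 methyltransferase encoded by Setdb1, driven by Cre recombinase from Emx2, a gene of dorsal forebrain progenitors. The comparison asks which transcripts of the developing cortex differ between these genotypes. Median intensities ran from 91.1 on WT 2 to 119 on cKO 3, and between 16.1% and 20.3% of the probe sets of an array were below an intensity of 16. Log2 values of array pairs correlated across probe sets at 0.96 or more, where probe sets are not independent replicates.

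The arrays numbered 3 stood apart from the others in both groups. WT 3, labelled male, had an Xist intensity of 17294 against 59.0 on WT 1 and 42.3 on WT 2, and Y-linked signals of 22.2 for Eif2s3y and 10.2 for Kdm5d, where WT 1 had 1927 and 934. cKO 3 had both kinds of signal, with Xist at 8811, Eif2s3y at 961 and Kdm5d at 663. Erythroid genes were also high on both arrays. The embryonic globin gene Hba-x, chosen after its values were seen, read 20068 on WT 3 and 19913 on cKO 3, and between 270 and 513 on the other 4 arrays. The median of 13 erythroid genes lay 2.15 (log2) above the other WT arrays on WT 3 and 2.18 above the other cKO arrays on cKO 3. The arrays were not alike in other lists. The meninges and mesenchyme list lay 0.94 above the other arrays of the group on cKO 3 and 0.21 on WT 3, the muscle list 0.71 and 0.26, and the ventral telencephalon list 0.32 and 0.68.

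**Figure D1:**
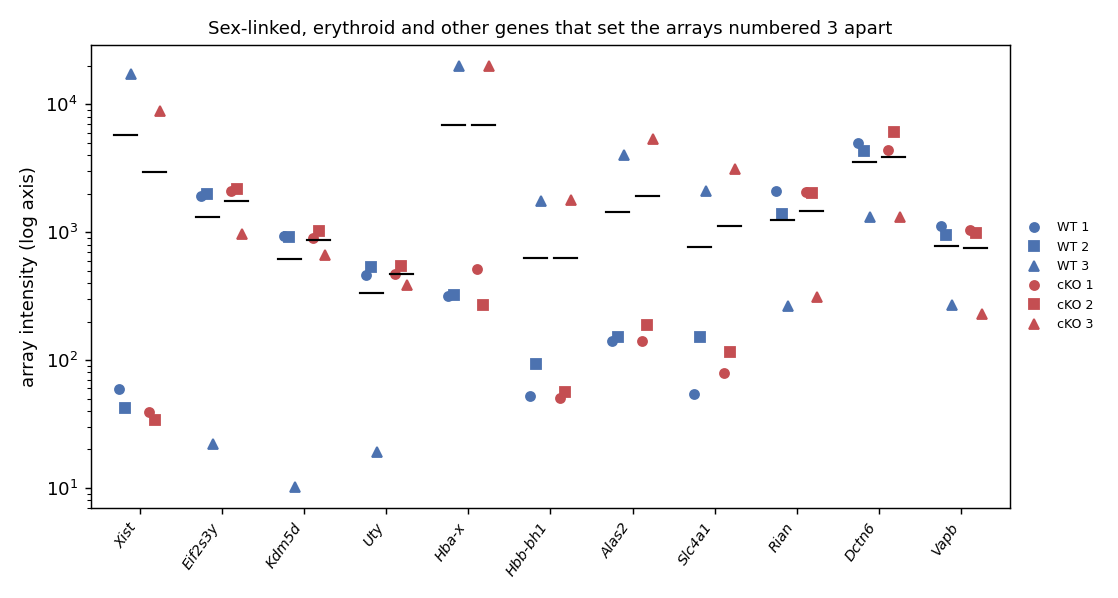
Array intensity (log axis) of sex-linked genes, erythroid genes and other genes in each of the 6 arrays, with colour for the group, marker shape for the array number and a bar for the mean of 3 arrays. Triangles are the arrays numbered 3, where Hba-x reads 20068 and 19913 and Rian, also chosen after its values were seen, reads 267 and 313.

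Setdb1 was lower in cKO on its brightest probe set, at 633 ± 115 (SD, n = 3) against 1126 ± 81.9 in WT, a log2 fold change of -0.83 (SE 0.17). Every cKO array, from 500 to 704, lay below every WT array, from 1033 to 1185. The difference did not pass the threshold over all genes (adjusted p = 0.137). Both other probe sets were near background in cKO, with means of 22.8 and 33.5, so the size of their fold changes is not given. On the first of these the groups did not overlap, and on the other they did. The labels do not say which exons are deleted, and a probe set outside the deleted part would not check the genotype.

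In the gene table, 70 genes rose and 44 fell in cKO past the threshold, with 3 arrays per group. Rises were larger. Their median log2 fold change was 2.00, against -1.41 for the genes that fell, and 42 of the 70 had a mean WT intensity below 100. All 114 genes had groups that did not overlap, as did 2828 of all 18193 genes, or 15.5%, where chance gives 10%. Among all 45037 probe sets, 101 rose and 23 fell, and with the arrays centred on their medians 97 rose and 41 fell. Of the 101, 19 had no gene in the annotation and 1 had several. Without a standard symbol were 12 of the risen genes and 5 of those that fell. Fits on fewer arrays have less power. Leaving out arrays cannot change the direction of a gene whose groups do not overlap, but the count fell. It was 33, 44 and 38 genes without WT 1, WT 2 and WT 3, and 32, 26 and 53 without cKO 1, cKO 2 and cKO 3. Without both arrays numbered 3 it was 8 genes, all of them among the 114.

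Of the 15 genes with the largest rise, Ddx4 and Stag3 belong to the germline list. The other genes described next have known roles in meiosis or germ cells but are not in that list, so this grouping was made after their values were seen and was not tested. Mnd1, which acts in meiotic recombination, went from 58.2 ± 5.60 in WT to 5821 ± 1108 in cKO (SD, n = 3), a log2 fold change of 6.28 (SE 0.17, adjusted p = 0.000115). Tcfl5, a transcription factor of the testis, went from 65.5 ± 9.61 to 4561 ± 66.7, a log2 fold change of 5.82 (SE 0.13, adjusted p = 6.9e-05). Ccnb3, a cyclin of meiotic cells, rose by 4.41 (SE 0.27). Ddx4, the germ cell RNA helicase known as Vasa, rose by 3.93 (SE 0.19), and Rnf17, a tudor domain protein of male germ cells, by 3.90 (SE 0.22). Stag3 and Rec8, subunits of meiotic cohesin, rose by 3.72 (SE 0.31) and 3.38 (SE 0.18), and Meioc, which is needed for meiosis, by 3.38 (SE 0.34).

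The other genes among the 15 largest rises have known roles outside the germ line or none named here. Tspan4, a tetraspanin, rose by 4.17 (SE 0.24) to 2266 ± 242, and Gramd1c rose by 4.03 (SE 0.26) to 1467 ± 430. The receptor genes Galr1, for galanin, and Tacr3, for neurokinin B, rose by 3.56 (SE 0.20) and 3.03 (SE 0.23). Tgif1, a homeodomain repressor of TGF-beta signalling, rose by 3.47 (SE 0.15), from 174 ± 27.2 to 2082 ± 130. Sec14l4 rose by 3.55 (SE 0.25) and Lhfpl3 by 3.29 (SE 0.44). In WT, the means of Ccnb3, Galr1, Sec14l4 and Meioc (8.70, 7.68, 9.14 and 7.64) were below the pseudocount of 16, which therefore sets the size and order of their fold changes. Meioc came to 5.89 with a pseudocount of 1, where it did not pass (adjusted p = 0.179), and to 1.95 with 64. Adjusted p over the 15 ran from 6.9e-05 to 0.042. In every fit that left out 1 array, 12 of the 15 stayed past the threshold, against 7 without both arrays numbered 3, 15 with those arrays as a block and 6 with the replicate block. Stag3 lost its call without cKO 1 or cKO 2, Meioc kept it in 1 of 6 such fits and Lhfpl3 in 1 of 6.

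**Figure D2:**
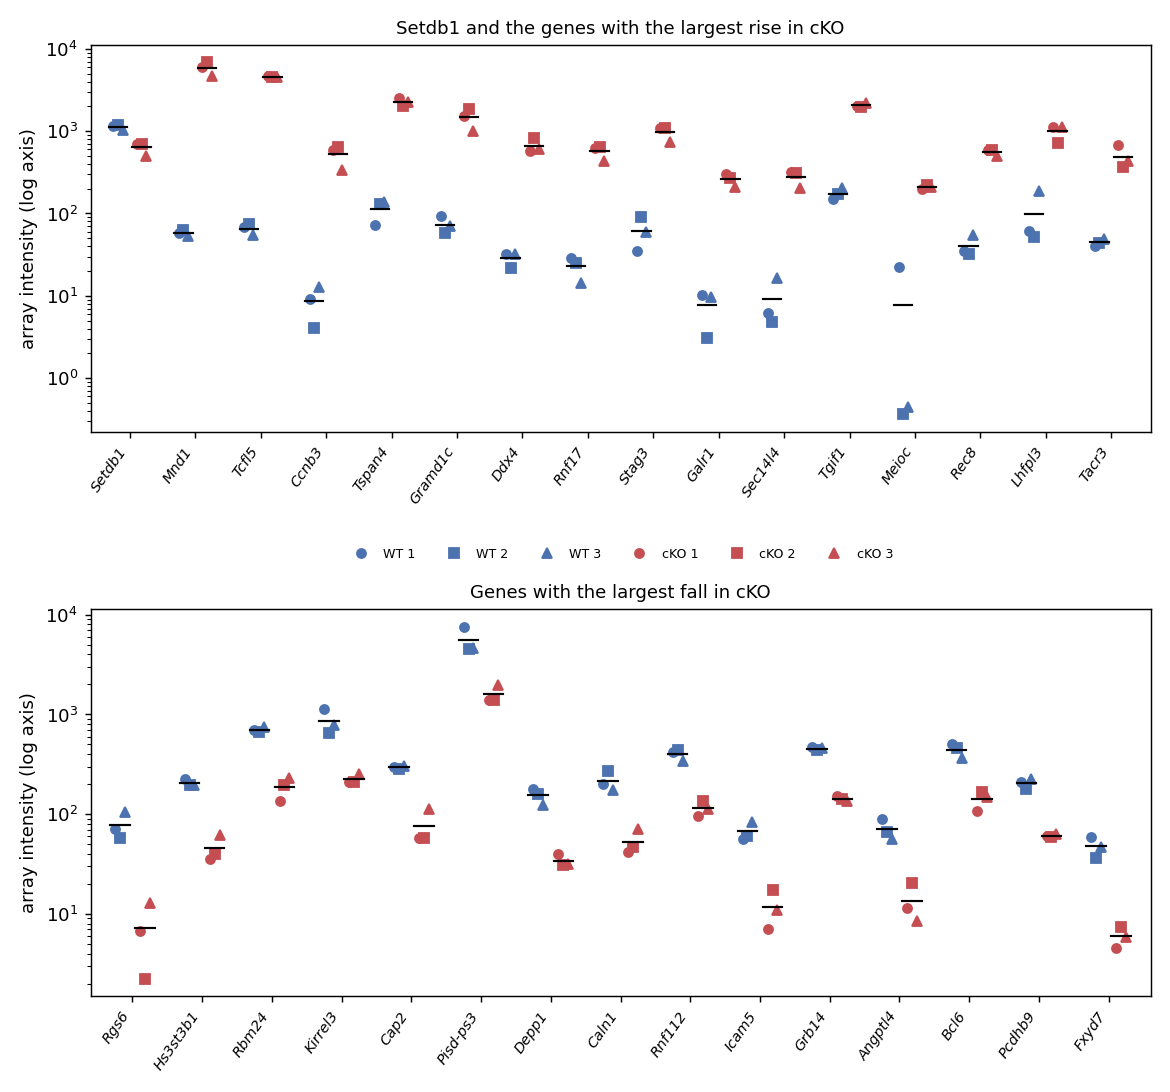
Array intensity (log axis) of Setdb1, of the 15 genes with the largest rise and of the 15 with the largest fall, with colour for the group, marker shape for the array number and a bar for the mean of 3 arrays. The cKO arrays of Mnd1 lie near 5821 and its WT arrays near 58.2, and the groups overlap for none of the genes drawn.

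Some risen transcripts had no standard name. These were chosen after their values were seen. Gm9222 went from 348 to 20520, and 2310043L19Rik from 20.1 to 3545. Probe sets without a gene went from 553 to 30931 and from 287 to 18366. These probe sets and that of Gm9222 have names ending in _x_at, with log2 fold changes of 5.82, 5.95 and 5.90. Whether they read separate transcripts was not tested.

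The 15 genes with the largest fall are given without a grouping. Kirrel3, an adhesion molecule of the immunoglobulin family, fell by 1.83 on the log2 scale (SE 0.22), from 856 ± 250 to 223 ± 23.7 (SD, n = 3). Icam5, an adhesion molecule of telencephalic neurons, fell by 1.59 (SE 0.20), and Pcdhb9, a clustered protocadherin, by 1.53 (SE 0.13). Rgs6, a regulator of G protein signalling, had the largest fall, by 2.01 (SE 0.25), at a WT intensity of 77.8. Hs3st3b1, a heparan sulfate sulfotransferase, fell by 1.87 (SE 0.19), and Rbm24, an RNA-binding protein, by 1.87 (SE 0.20), from 706 ± 41.2 to 186 ± 47.6. Bcl6, a transcriptional repressor that promotes neurogenesis, fell by 1.55 (SE 0.20), and Grb14, an adaptor of insulin receptor signalling, by 1.57 (SE 0.11), from 455 ± 15.2 to 143 ± 7.14. Cap2, Pisd-ps3, Depp1, Caln1, Rnf112, Angptl4 and Fxyd7 fell by between 1.52 and 1.82.

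The cKO means of Rgs6, Icam5, Angptl4 and Fxyd7 (7.25, 11.8, 13.4 and 5.94) were below the pseudocount, which sets the size and order of their falls, and with a pseudocount of 1 Rgs6, Icam5 and Angptl4 did not pass (adjusted p = 0.120, 0.0879 and 0.101). With a pseudocount of 64 the fall of Rgs6 came to -0.98. Adjusted p over these 15 genes ran from 0.00460 for Grb14 to 0.0496 for Pisd-ps3. Most of these calls were lost in some fit that left out 1 array, where fewer arrays also lower the power. All 15 genes stayed lower in cKO in these fits, as groups that do not overlap must. Grb14 passed in all 6 fits that left out 1 array, Pcdhb9 in 3, and 7 genes (Rgs6, Kirrel3, Pisd-ps3, Caln1, Icam5, Angptl4 and Bcl6) in none. Of the others, Rbm24 passed in 2 such fits, and Hs3st3b1, Cap2, Depp1, Rnf112 and Fxyd7 in 1 each. Without the arrays numbered 3, 0 of the 15 passed, against 10 with those arrays kept as a block and 1 with the replicate block. Over all genes, limma then called 8, and 1779 had an unadjusted p below the threshold. Another probe set of Angptl4 gave a log2 fold change of 0.23. Further probe sets of the other sign existed for 6 of 34 risen genes and 7 of 27 fallen genes that had more than 1 probe set.

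Of the 26 gene lists, 7 passed the threshold with the preset correlation, 1 upward and 6 downward. With an estimated correlation 0 passed, and fry called 5 of them in the same direction. The estimates for the germline (-0.02), endothelium and pericyte (-0.05) and upper layer (0.0006) lists lay below the preset 0.01. A correlation above the preset value therefore does not account for the loss of those calls. Medians below are log2 fold changes of the members.

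The germline list rose, with a median of 0.31 over 43 measured genes (adjusted p = 9.6e-08, and adjusted p = 0.0561 with an estimated correlation). Of these genes, 6 rose and 0 fell past the threshold over all genes, and 11 rose when adjusted over the list alone. Beside Ddx4 and Stag3, these were Slc25a31, a testis ADP/ATP carrier, at 2.65 (SE 0.15), Mael, of the piRNA pathway, at 2.73 (SE 0.20), and Tex101, a germ cell surface protein, at 1.59 (SE 0.11). The sixth was Sycp3, a synaptonemal complex protein at 2.46 (SE 0.20), named after its value was seen. WT means of Slc25a31, Mael and Tex101 were below the pseudocount, which sets the size of their rises, and Mael did not pass with a pseudocount of 1 (adjusted p = 0.0752). The list median was not shifted on the arrays numbered 3, by 0.02 on WT 3 and 0.06 on cKO 3 against the other arrays of the group.

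The clustered protocadherins, neuronal adhesion molecules encoded in tandem arrays, fell as a list, with a median of -0.62 over 23 measured genes (adjusted p = 2.7e-06, and adjusted p = 0.0777 with an estimated correlation). Of 58 genes written in the list, those measured were 22 of the beta cluster and 1 of the gamma cluster, so the alpha cluster and most of the gamma cluster were not tested. Past the threshold over all genes 3 fell, all of the beta cluster. Pcdhb9 went from 205 ± 22.9 to 60.7 ± 2.90, Pcdhb21 fell by 1.51 (SE 0.21) and Pcdhb19 by 1.24 (SE 0.17). Pcdhb9 lost its call without WT 1, cKO 1 or cKO 2, and the other two lost theirs in each fit that left out 1 array (lowest adjusted p = 0.0573 and 0.0663). Adjusted over the list alone, 7 fell, all of the beta cluster, and 1 rose. The latter was the gamma gene Pcdhgc4, at 0.89 (SE 0.26), named after its value was seen and short of the threshold over all genes. Pcdhb22, at -1.33 (SE 0.24), did not pass over all genes.

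Genes of Cajal-Retzius cells, the early neurons of the cortical surface that secrete reelin, fell as a list, with a median of -0.37 over 14 measured genes (adjusted p = 7.1e-06, and adjusted p = 0.0790 with an estimated correlation). Past the threshold over all genes 1 fell. This was Reln itself, from 6345 ± 184 to 2856 ± 345 (log2 fold change -1.15, SE 0.14, adjusted p = 0.0266). In the fits that left out 1 array it ran from -1.24 to -1.06 and did not pass (lowest adjusted p = 0.0587). Adjusted over the list alone 4 fell and 0 rose. The members next by p were Ndnf at -1.34 (adjusted p = 0.0504), Lhx5 at -1.05 and Trp73 at -1.14. The list lay 0.14 above the other arrays of the group on WT 3 and 0.26 on cKO 3.

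Both cortical layer lists passed downward. The upper layer list had a median of -0.31 over 16 genes (adjusted p = 9.5e-05, and adjusted p = 0.0777 with an estimated correlation). In it limma called 0 genes over all genes, where 5 were lower and 0 higher at an unadjusted p under 0.05, and 3 fell when adjusted over the list alone. Members with the smallest p were Rorb at -1.09, Mef2c at -0.90, Kitl at -0.44 and Inhba at -0.57. Rasgrf2, named after its values were seen, was at -0.16 in the gene table. Another of its probe sets rose past the threshold over all probe sets (1.49, adjusted p = 0.0303), from a WT mean of 13.9, below the pseudocount. The deep layer list had a median of -0.10 over 19 genes (adjusted p = 0.0467, and adjusted p = 0.536 with an estimated correlation), and its members parted. Crym, a thyroid hormone binding protein of deep layer neurons, rose by 2.84 (SE 0.30), from 232 ± 97.9 to 1685 ± 304, while Nr4a2, an orphan nuclear receptor, fell by 1.18 (SE 0.17). Adjusted over the list alone 2 rose and 5 fell. Crym kept its call only without WT 2 among the fits that left out 1 array, and Nr4a2 in none (lowest adjusted p = 0.108). Lmo3 was at -0.88, short of the threshold. Over the fits that left out 1 array, the deep layer median ran from -0.23 to -0.05. The deep layer call ended without WT 1 (adjusted p = 0.109), without WT 2 (0.085) and without cKO 1 (0.258). It also ended with the arrays numbered 3 as a block (adjusted p = 0.0583) and with the replicate block (adjusted p = 0.0659).

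The endothelium and pericyte list fell, with a median of -0.29 over 21 genes (adjusted p = 2.4e-06, and adjusted p = 0.0604 with an estimated correlation). Over all genes limma called 0, where 7 were lower and 0 higher at an unadjusted p under 0.05, and adjusted over the list alone 4 fell, Abcc9 at -1.05, Tie1 at -0.85, Emcn at -0.46 and Rgs5 at -0.60. The cell cycle list fell by less, with a median of -0.16 over 35 genes (adjusted p = 2.5e-05, but adjusted p = 0.536 with an estimated correlation of 0.23, and fry adjusted p = 0.141). In it limma called 0 genes with either adjustment, where 2 were lower and 0 higher at an unadjusted p under 0.05. Ccne2 was at -0.63, Ccnd2 at -0.52, Birc5 at -0.31 and Aurka at -0.27.

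**Figure D3:**
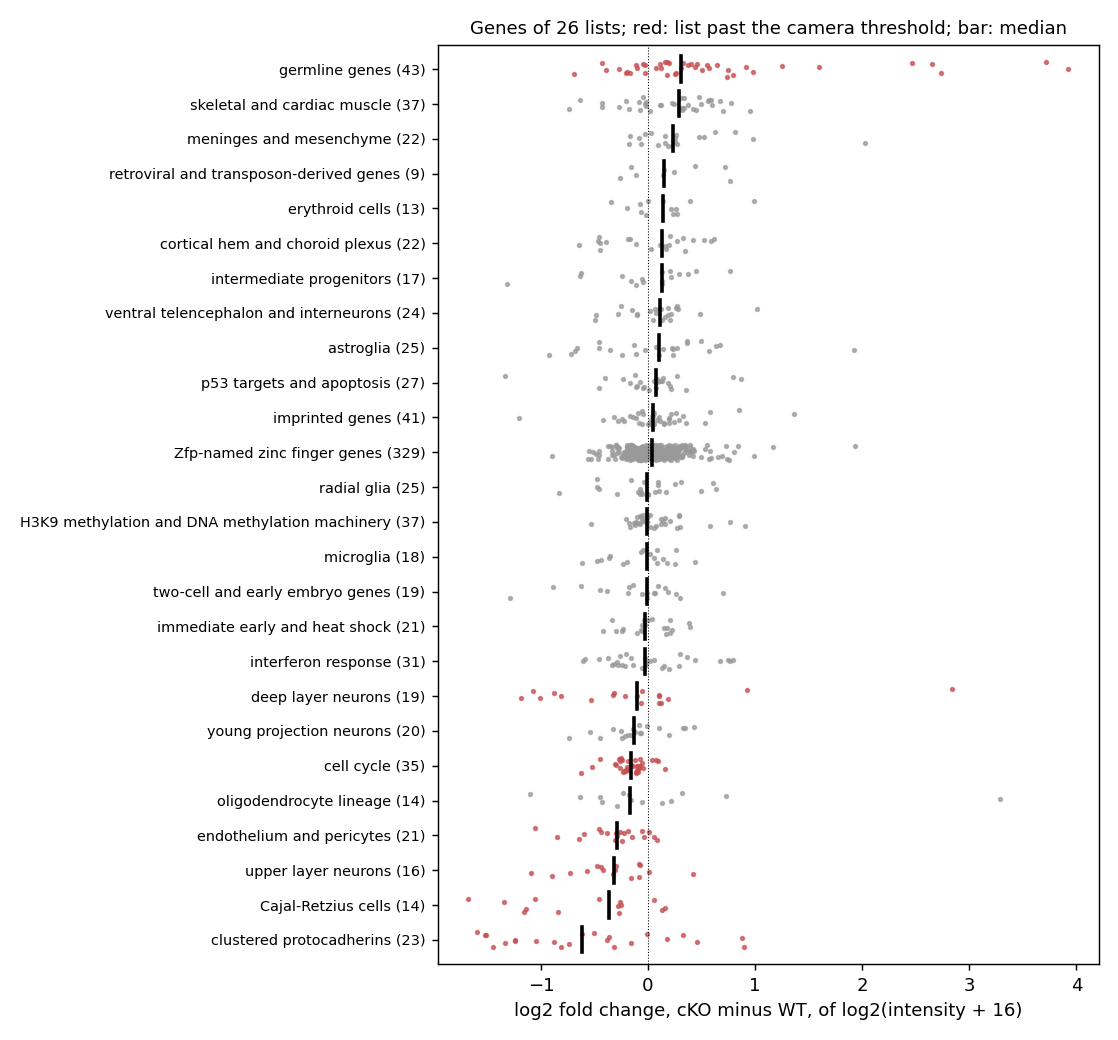
Log2 fold change (cKO minus WT, of log2 intensity plus 16) of each measured gene in 26 lists, with the number of genes in brackets and a bar for the list median. Lists past the threshold are red, from the clustered protocadherins with a median of -0.62 to the germline genes with a median of 0.31.

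The lists of radial glia, intermediate progenitors and young projection neurons did not pass. Adjusted over the list alone, 1 radial glia gene fell, 1 gene of intermediate progenitors rose and 2 fell, and 0 of young projection neurons did either, where 1 was higher and 2 lower at an unadjusted p under 0.05. Radial glia, the stem cells of the cortex, had a median of -0.01 over 25 genes (adjusted p = 0.725). Emx2, after which the Cre line is named, was at -0.83 (SE 0.14, adjusted p = 0.0714) with no overlap, Ddah1 at -0.48, Ttyh1 at 0.50 and Tfap2c at -0.45. Whether the WT embryos carried Cre is not given here. An effect of the Cre allele can therefore not be told apart from that of the deletion, for Emx2 or other genes. Intermediate progenitors had a median of 0.13, a mean of -0.03 and a test pointing down (adjusted p = 0.978). Neurog1, at -1.32 (SE 0.19, adjusted p = 0.0543), and Eomes, at -0.63, were lower, and Nhlh1, at 0.77, and Dll1, at 0.38, were higher, each short of the threshold over all genes. Young projection neurons had a median of -0.13 (adjusted p = 0.133), with Mapt at -0.54, Gap43 at -0.33, Slc17a7 at 0.43 and Syt1 at -0.25.

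Glial lists had no common direction. When adjusted over the list alone, 1 astroglia gene rose and 1 fell, and 1 oligodendrocyte gene rose. The astroglia list had a median of 0.10 (adjusted p = 0.725). In it Sparcl1 fell by 0.92 (SE 0.12, adjusted p = 0.0380). In the fits that left out 1 array it ran from -0.96 to -0.86 and did not pass (lowest adjusted p = 0.114). Sox9, a transcription factor of glial progenitors, read 625 ± 243 in WT and 2338 ± 482 in cKO (log2 fold change 1.92, SE 0.30, adjusted p = 0.0640). Fgfr3 was at 0.63 and Ntsr2 at 0.49. The oligodendrocyte list had a median of -0.17, a mean of 0.08 and an adjusted p of 0.725. It holds Lhfpl3, which rose, while Olig2 was at -1.10, Mbp at 0.32 and Gpr17 at -0.63, all short of the threshold. The cKO mean of Gpr17 was below the pseudocount.

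Lists of cells at the edge of the dissected region and of other tissues did not pass either. Adjusted over the list alone, limma called 1 gene of the meninges, upward, and 0 of the others, where 2 ventral genes and 1 erythroid gene were higher and 2 hem genes lower at an unadjusted p under 0.05. The ventral telencephalon and interneuron list had a median of 0.11 (adjusted p = 0.358), with Gad1 at 0.48, Nkx2-1 at 1.01, Lhx6 at 0.19 and Maf at 0.27. It passed upward without WT 3 (median 0.27, adjusted p = 0.00189) and without both arrays numbered 3 (median 0.18, adjusted p = 0.0196). The cortical hem and choroid plexus list had a median of 0.13 (adjusted p = 0.978), with Ttr at -0.64, Rspo3 at -0.47, Car12 at -0.45 and Foxj1 at 0.33. Microglia had a median of -0.01 (adjusted p = 0.671), with P2ry12 at -0.44, Cx3cr1 at -0.47, Trem2 at -0.62 and Laptm5 at -0.35. Meninges and mesenchyme had a median of 0.23 (adjusted p = 0.133). Cyp1b1 of that list rose by 2.03 (SE 0.25) from a WT mean below the pseudocount (13.5), but kept its call only without cKO 1 among the fits that left out 1 array and lost it with a pseudocount of 1 (adjusted p = 0.0567), Foxc2 was at 0.98, Postn at 0.63 and Col6a1 at 0.52. That list passed upward without WT 3, cKO 1 or cKO 2 (adjusted p = 0.0457, 0.00191 and 0.0116). Without both arrays numbered 3 it did not pass (median 0.01, adjusted p = 0.992). Erythroid cells had a median of 0.14 (adjusted p = 0.725), with Hba-a1 at 0.99, Klf1 at 0.27, Hemgn at -0.35 and Epb42 at 0.39, and passed upward without WT 3 (median 0.98, adjusted p = 0.0357). Without both arrays numbered 3 the erythroid list did not pass (median 0.04, adjusted p = 0.992). Skeletal and cardiac muscle had a median of 0.29 (adjusted p = 0.174), with Casq1 at 0.47, Myf6 at 0.45, Tnnc2 at 0.95 and Chrna1 at -0.64, and passed upward without WT 3 (adjusted p = 0.0371) or cKO 2 (adjusted p = 0.00772). The WT means of Nkx2-1, Foxc2, Hba-a1, Myf6 and Tnnc2 were also below the pseudocount, which sets the size of their fold changes.

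Lists tied to silencing and to stress did not pass as groups. Adjusted over the list alone, 1 gene of the H3K9 machinery, 1 Zfp gene and 1 p53 gene rose, and 1 imprinted gene and 2 early embryo genes fell. Imprinted genes had a median of 0.05 over 41 genes, below 0 with centred arrays (adjusted p = 0.725), with Nap1l5 at -1.21 (adjusted p = 0.0504), Cdkn1c at 1.36, Ascl2 at 0.85 and Snrpn at -0.42. The H3K9 and DNA methylation machinery had a median of -0.01, above 0 after quantile normalization, a mean of 0.07 and an adjusted p of 0.410. Its members with the smallest p were higher in cKO but short of the threshold. Tasor, of the HUSH silencing complex, was at 0.91, Atf7ip, a partner of ESET, at 0.76, Zfp809, which silences proviruses, at 0.58, and Kdm3a at 0.29. Genes with Zfp names, many of them zinc finger repressors, had a median of 0.04 over 329 genes, below 0 with centred arrays (adjusted p = 0.358). Zfp991 rose by 1.93 (SE 0.16), a call lost without cKO 1 or cKO 2, and Zfp110 was at 1.17, Zfp33b at 0.76 and Zfp369 at 0.84. The retroviral and transposon-derived list had a median of 0.15 over 9 genes (adjusted p = 0.358), with Erv3 at 0.76, Fv1 at 0.44, Arc at 0.72 and Pnma2 at -0.16. Early embryo genes had a median of -0.01 (adjusted p = 0.358), with Arg2 at -1.29, Eomes at -0.63, Elf5 at 0.70 and Pramel7 at -0.89. The 2 that fell when adjusted over the list alone were Arg2 and Eomes, which is also in the intermediate progenitor list. The interferon list had a median of -0.03, a mean of 0.01 and an adjusted p of 0.977, with Ifit3 at 0.76, Bst2 at 0.75, Ifi35 at -0.38 and Oas3 at 0.68. The p53 list had a median of 0.07 and a test pointing down (adjusted p = 0.977), with Fas at 0.87, Pmaip1 at -1.34, Plk2 at -0.46 and Casp9 at -0.40. Immediate early and heat shock genes had a median of -0.03, a mean of 0.00 and an adjusted p of 0.977, with Ier3 at 0.39, Dusp1 at -0.33, Hspa8 at -0.30 and Jun at 0.39. In WT, the means of Fas, the p53 gene that rose, and of Elf5, Ascl2, Erv3, Arc and Oas3 were below the pseudocount. So were the cKO means of Pramel7 and Pmaip1. The pseudocount therefore sets the size of these fold changes.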

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

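The fits without the arrays numbered 3, with those arrays as a block and with Xist as a covariate were chosen after seeing the data. Of 2492 values of 135 named genes under alternatives, 2163 kept their side of the threshold, 255 lost a call and 73 gained one. Values short of the threshold in both fits counted as kept even where their sign changed. The remaining 1 reversed, which was Angptl4 at 0.23 without probe sets ending in _x_at or _s_at, where another probe set stands for the gene. Of 541 list values, counted in the same way, 510 kept their side, 19 lost a call and 12 gained one. Counts are given below as risen and fallen.

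Genes, 70 and 44 as reported, came to 129 and 123 above the median mean, where 10688 genes were tested and dim probe sets were left out, 45 and 13 with a pseudocount of 1, 125 and 90 with 64, 135 and 109 with trend and robust eBayes, and 108 and 81 with array weights. The mean of a gene's probe sets left 19 fallen. Probe sets, 101 and 23 as reported, came to 166 and 86 above the median mean, 41 and 7 with a pseudocount of 1, and 174 and 83 with trend and robust eBayes. Fallen probe sets came to 56 with a pseudocount of 64, 43 with array weights, 41 with centred arrays and 14 with Xist as a covariate. The causes of these changes were not tested, and above the median mean fewer genes and the loss of dim probe sets were not told apart. Leaving out 1 array gave 25 to 44 risen and 1 to 9 fallen genes, 19 to 34 risen and 0 to 2 fallen probe sets, and 6 to 11 lists. Without both arrays numbered 3 there were 8 and 0 genes and 8 and 0 probe sets, and with those arrays as a block 73 and 37 genes and 90 and 18 probe sets.

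The replicate block gave 16 and 1 genes, 7 and 0 probe sets, 6 lists and an unchanged Setdb1 value of -0.83. The labels do not say that numbers pair arrays. Deviations of same-numbered arrays correlated at 0.08, 0.19 and 0.41, and WT 1 correlated best with cKO 2, so the numbers were not taken as pairs. Setdb1 stayed between -0.91 and -0.67 in every alternative. It passed the threshold above the median mean (-0.83, adjusted p = 0.0377) and with trend and robust eBayes (-0.83, adjusted p = 0.0308), within a range up to 0.377. Camera with an estimated correlation called 0 lists, where fry called 5. Dim probe sets, with 16.1% to 20.3% below an intensity of 16, limit the fold changes of genes near background.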

Other observations

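The tests on neighbouring genes, on the sex-linked genes, on the arrays numbered 3 and on the Cajal-Retzius list were chosen after the result was seen, and the list of the amino acid response was written after Chac1 and Asns had been seen. The genes named from that list and from the neighbouring pairs were picked for the text after their values were seen, apart from Rbm24, Cap2 and Icam5.

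Genes that respond to amino acid shortage through the transcription factor ATF4 were higher in cKO as a group. The list was written after Chac1, a glutathione-degrading enzyme at 1.89 (SE 0.19, adjusted p = 0.0156), and Asns, asparagine synthetase at 1.18 (SE 0.14, adjusted p = 0.0310), had been seen past the threshold. Of the other 29 members, 24 were higher in cKO and 0 passed over all genes. Their median log2 fold change was 0.30, above all of 10000 random lists matched on mean expression (percentile 100). In the other 9 splits of the 6 arrays the same median ran from -0.17 to 0.18. Those splits mix the genotypes, so a genotype difference enters them only in part. They therefore give no range for a list without such a difference. Members near the threshold were Cars, a cysteinyl-tRNA synthetase, at 0.80 (adjusted p = 0.0725), and Slc7a5, a transporter of large amino acids, at 0.88 (adjusted p = 0.0869). Eif4ebp1 was at 1.16 (adjusted p = 0.150), and Atf4 itself at 0.30 (adjusted p = 0.464). The random lists leave out the correlation between genes of one response. That ATF4 targets are raised in cKO tissue is a hypothesis from these data, and it may or may not follow from the deletion.

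Genes that changed lay next to each other more often than chance places them. Among 18145 tested genes put in the order of assembly GRCm38.p6, 4 pairs of risen genes were neighbours, where 10000 random lists of 70 genes held 0.27 on average and 3 at most (permutation p = 0.0001, the smallest these draws can give). The pairs were Gm9222 and 5730507C01Rik, Adamts1 and Adamts5, Mcfd2 and 4833418N02Rik, and Znf41-ps and Gm13238. Of the genes that fell, 3 pairs were neighbours (permutation p = 0.0003, random mean 0.10). These were Rbm24 and Cap2, Lhfp and C130075A20Rik, and Icam4 and Icam5. A candidate explanation is that ESET loss acts on stretches of chromosome, and another is that neighbouring probe sets read parts of 1 transcript. The counts of 4 and 3 pairs do not separate these.

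WT 3 carried Xist and almost no Y-linked signal, and cKO 3 carried both. On WT 3 the highest of 3 Y-linked genes stood at 3.86% of the mean of WT 1 and WT 2, so female RNA on an array labelled male is consistent with these values. On cKO 3 the Y-linked genes stood at 44.8% to 75.2% of the mean of cKO 1 and cKO 2 beside an Xist intensity of 8811, which is consistent with a mixture of female and male RNA. A rise of Xist through the loss of ESET is argued against, since the highest Xist intensity on cKO 1 and cKO 2 was 39.5, below the 59.0 of WT 1. Where female RNA entered the samples stays open.

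The arrays numbered 3 deviated from the others together, and the scaling of the arrays is argued against, since the correlation of deviations of WT 3 and cKO 3 across probe sets was 0.40 after quantile normalization. For sex as the whole cause, shifts along the first principal component were compared. There cKO 3, with 50.9% of the Xist of WT 3, had moved 1.04 times as far, and at least 0.88 times for any choice of reference arrays. This does not decide it, since log2 shifts need not follow the share of female RNA. Against the other arrays of the group, Xist was at 8.03 (log2) on WT 3 and 7.39 on cKO 3. Eif2s3y was at -5.69 and -1.14. Blood cell RNA as the whole cause is argued against, since it would lower other genes alike, while the median gene with a mean intensity above 200 moved by -0.05 and 21 such genes outside the erythroid and sex-linked lists fell by 1 or more (log2) on both arrays, against at most 1 between the arrays numbered 1 and 2. Intensity limits were chosen after the counts were seen, and the counts were 27 against 9 above 50, 24 against 1 above 100, 19 against 0 above 500, and 37 against 60 with no limit, where genes near background enter. A shared processing batch may account for it, but the labels name no batch, so it cannot be told apart from differences between embryos. The correlation was 0.39 without the erythroid and sex-linked lists, against at most 0.19 for other pairs across the groups. This value does not separate a batch from blood, since genes outside those lists rose with the erythroid genes. The globin gene Hbb-b2, chosen after its values were seen, lay 3.64 (log2) higher on WT 3 and 5.27 on cKO 3.

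The Cajal-Retzius list was lower in cKO. A dissection that held less of the medial edge of the cortex, where many of these cells arise, would lower the hem and choroid plexus list too. That list lay 0.50 (log2) above the Cajal-Retzius list, with a 95% bootstrap interval over genes from 0.10 to 1.26, and among members with a WT intensity above 50 the difference was 0.61 with an interval from 0.08 to 1.35, but above 100 it was 0.34 with an interval from -0.19 to 1.30, and while 13 of the 22 hem members were higher, the 3 with the smallest p were lower (Ttr at -0.64, Rspo3 at -0.47 and Car12 at -0.45), so this stays open. Of 14 markers, 11 (78.6%) were lower, and a smaller share of these cells cannot be told apart from lower expression per cell without cell counts. An effect of the genotype is untested beyond these arrays.

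The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.1. The real split gave 114 genes and the highest of the others 0, and 124 probe sets against 0. It gave 7 gene lists against 6, the latter for WT 1, WT 3 and cKO 3 against the rest. In each case 1 of the 10 splits, the real one, gave as many. Every other split mixes the genotypes within its groups, so a genotype difference adds to the spread there. Their counts therefore give no range for arrays without such a difference.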
